A study of Homo sapiens with 4 samples.

How the data were processed

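Binding labelled as that of HNF1 (hepatocyte nuclear factor 1, a homeodomain transcription factor family) was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq). The cells were Caco2, a human colorectal adenocarcinoma line used as a model of intestinal epithelium. The labels describe 4 libraries, namely 2 HNF1 immunoprecipitations and 2 inputs made without antibody. The 2 immunoprecipitations each came with 1 peak list. Each list was called against the input library of the same replicate number, per the labels, so the inputs entered only through that calling. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical. The antibody field of both immunoprecipitations names an HNF1 antibody, whereas the extraction text of all 4 libraries names a FOXA2 antibody. The field also gives a catalogue number, whose target was not checked here. The libraries are called HNF1 libraries here after the antibody field and the titles.

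Per the submitters' processing notes, Bowtie 1.0.0 and HOMER 1.2 were used with the hg19 genome build. The notes list these names without their roles. One peak of replicate 1 ends at position 59017148 of chromosome Y, in the coordinates of the deposited list. Per the file headers, peaks were called on each library separately with HOMER findPeaks in its factor mode. The headers give a false discovery rate of 0.001, at least 4-fold more tags than in the input and than in the surrounding 10000 bp, and Poisson p limits of 0.0001. The fragment length was 76 bp in replicate 1 and 226 bp in replicate 2, per the file headers. The peak size was 142 bp in replicate 1 and 226 bp in replicate 2, and the tag threshold was 9 and 13 tags per peak. Peaks were centred on the highest tag pile-up, and closer neighbours than 284 bp in replicate 1 or 452 bp in replicate 2 were not called. These settings differ between the replicates, so an equal tag density could pass in one list and not in the other.

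The score deposited with each peak is HOMER's tag count scaled by the authors' run to 10000000 tags and rounded to a whole number. One tag was worth 0.838 score units in replicate 1 and 0.541 in replicate 2. The scores of a list summed to 1.002 times the header's scaled tags in peaks in replicate 1 and to 1.006 times in replicate 2. Scores were used to rank and describe peaks within a list and to correlate shared pairs, and were not treated as counts. Ratios of scores between the lists also carry the difference in tag window and calling settings. Other columns named in the headers, such as the fold over input, were not used here. The deposited start positions count from 0, and all positions in the text count from 1.

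A peak was called shared when it overlapped a peak of the other replicate by at least 1 bp. Overlapping peaks were joined into shared regions. The number shared was tested one-sided against 1000 circular shifts of the replicate 2 peaks within each chromosome, along the span from the first to the last peak of both lists. Shares carry Wilson 95% intervals, which cover counting error only, and peaks are not independent replicates. Scores of shared pairs were compared by Pearson's r and Spearman's rho with 100000 permutations, two-sided. Medians were compared by 100000 permutations with intervals from 1000 bootstrap samples. The spread of peaks over chromosomes was compared by a chi-square statistic with 100000 permutations of list membership, and single chromosomes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 24 chromosomes. Shared peaks stand in both lists, so these chromosome tests treat as separate what was partly seen in common. They compare the 2 libraries and not conditions.

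The main comparisons, part of their other settings and the rule for naming regions were fixed before the data were examined, and the closing section names the settings and tests that were added later. The rule took the 10 shared regions with the best score ranks, ordered by the worse of the 2 ranks. Tests of promoter location, of 8 transcription factor motifs and of 14 gene lists were planned for the case that an hg19 annotation and sequence were at hand. None was used here, so these were not run, regions are given by hg19 position and no gene is named. The overlap, correlation and chromosome procedures were tested on simulated data. At 5060 simulated peaks with 20% or 60% of them shared, the overlap came out as 20.0% and 60%. The simulated partners were placed close enough to overlap by construction. This checked the counting and not the loss of partners through displacement or calling. With 100 of 4955 peaks moved to chromosome 20, the chromosome test passed 0.05 in 74% of 50 runs, and with no difference in 4% of 100 runs. These simulated lists were drawn independently, whereas the real lists hold many peaks in common. The rates therefore do not describe the chromosome test on the real lists. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.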

Results

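Binding labelled as HNF1 in Caco2 cells was profiled to learn which parts of the genome the factor occupies in an intestinal epithelial line. The antibody was an HNF1 antibody by its own label, while the extraction text names one against FOXA2. Nothing run here settles which target applies, and the HNF1 name only follows the antibody field and the titles. Replicate 1 was sequenced to 11931439 tags and replicate 2 to 18469659 tags, which was 1.55 times as many. The deposited lists held 5060 peaks in replicate 1 and 4955 peaks in replicate 2. All peaks of a list had 1 width, 143 bp in replicate 1 and 227 bp in replicate 2, so that the lists covered 724 kb and 1125 kb of the genome. Peaks held 96590 tags in replicate 1 and 126892 tags in replicate 2, and the headers put the efficiency of the immunoprecipitation at 0.81% and 0.69% of tags. The score of a peak is its number of tags scaled to 10000000 tags per library, and its median was 12 in replicate 1 (quartiles 8 and 18) and 11 in replicate 2 (quartiles 9 and 16). With 1 list per library, no standard deviation can be given, and the comparison of the 2 lists is the replicate check.

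The first question was which sites were bound in both replicates. A total of 2905 regions were shared, 2153 peaks were found in replicate 1 alone and 2050 in replicate 2 alone. The shared regions made up 40.9% of the 7108 distinct regions. Seen from replicate 1, 2907 peaks overlapped a replicate 2 peak, or 57.5% of the list (95% interval 56.1% to 58.8%). Seen from replicate 2, 2905 peaks overlapped a replicate 1 peak, or 58.6% (57.25% to 59.99%). Shifting the replicate 2 peaks along their chromosomes left a mean of 3.48 overlapping replicate 1 peaks and at most 13 in 1000 shifts (permutation p = 0.001, the smallest these shifts can give). Within shared pairs the median distance between midpoints was 27 bp, and 93.8% of the 2907 pairs had midpoints within 100 bp. The overlap rule itself keeps this distance under 190 bp.

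Of the 50 highest scored peaks, 41 of replicate 1 and all 50 of replicate 2 had a partner in the other list. The 3 highest scored peaks of replicate 1, on chromosomes 21, 12 and 17, had none. The following 10 regions were chosen among the shared ones by their ranks. The region with the best ranks lay on chromosome 2 at 62797219 to 62797490 and scored 125 in replicate 1 and 113 in replicate 2. A region on chromosome 5 at 145358925 to 145359151 scored 113 and 93. On chromosome 17, the region at 46873119 to 46873345 scored 117 in replicate 1 and 77 in replicate 2. The region on chromosome 10 at 60833349 to 60833575 scored 101 and 81. Of 2 regions on chromosome 20, the one at 30196523 to 30196749 scored 113 and 63, and the one at 62655670 to 62655896 scored 93 and 76. Chromosome 2 held 2 further regions of this set, at 43421375 to 43421601 with scores of 107 and 60, and at 43206830 to 43207058 with scores of 82 and 57. The set was completed by a region on chromosome 12 at 4124578 to 4124804, which scored 94 and 58, and by a region on chromosome 11 at 114080752 to 114080978, which scored 78 and 62. All 10 regions ranked among the 50 highest scored peaks of both lists, as did 20 shared regions altogether. The gene annotation of these positions was not used here.

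Recurrence was more frequent at higher scores, except at the very top of replicate 1. In the lowest score decile, 29.2% of replicate 1 peaks had a partner (25.5% to 33.4%), and in the highest decile 93.9% did (91.4% to 95.7%). In replicate 2 the corresponding shares were 24.8% (21.2% to 28.8%) and 97.2% (95.3% to 98.3%). The lowest 3 deciles of replicate 1 stood at 29.2%, 29.1% and 31.2%, but their bounds split peaks with the same rounded score of 8. Within its highest decile the share was 93.8% of the 500 highest scored peaks, 89% of the highest 100 and 82% of the highest 50 (69.2% to 90.2%), against 97%, 99% and 100% in replicate 2. Shared peaks of replicate 1 had a median score of 15 against 9 in peaks found in replicate 1 alone, a difference of 6 (95% bootstrap interval 6 to 7, permutation p = 1e-05). In replicate 2 the medians were 14 and 9, a difference of 5 (5 to 5, permutation p = 1e-05). Both p-values are the smallest that 100000 permutations can give. The upper quartile of the peaks found in 1 library was a score of 12 in replicate 1 and 11 in replicate 2. The tag thresholds of the calling, scaled in the same way, corresponded to 7.54 and 7.04. The lowest deposited score was 6 in both lists, so these values were not a floor of the scores.

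**Figure D1:**
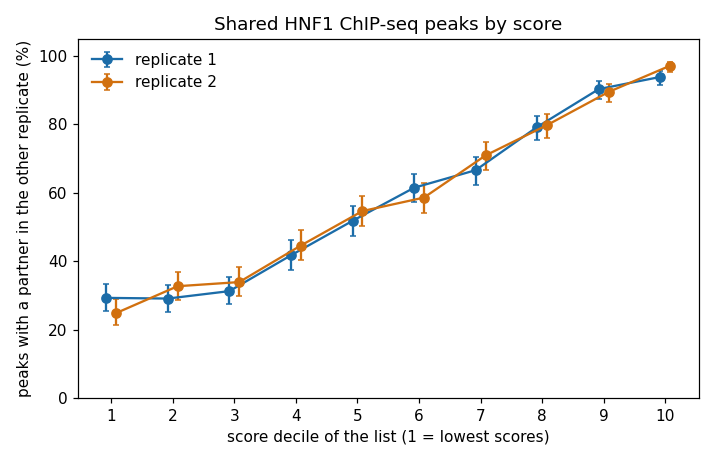
Share of peaks (%, y axis) that overlapped a peak of the other replicate, by score decile of the list (x axis, 1 the lowest scores), for replicate 1 (blue) and replicate 2 (orange), with Wilson 95% intervals as bars. The share is 29.2%, 29.1% and 31.2% in the lowest 3 deciles of replicate 1 and reaches 93.9%, and it goes from 24.8% to 97.2% in replicate 2.

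Across the 2907 shared pairs, which are peaks and not independent replicates, the scores of the replicates were correlated, with Pearson's r of 0.67 and Spearman's rho of 0.60 (permutation p = 1e-05 for each, the smallest these permutations can give). The scores of replicate 1 were higher by a median log2 ratio of 0.17. That ratio cannot be read as a difference in occupancy, because each replicate is 1 library and the calling settings differed. Tags were counted in windows of 142 bp in replicate 1 and 226 bp in replicate 2. The narrower window would by itself lower the scores of replicate 1, so it does not account for this direction.

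**Figure D2:**
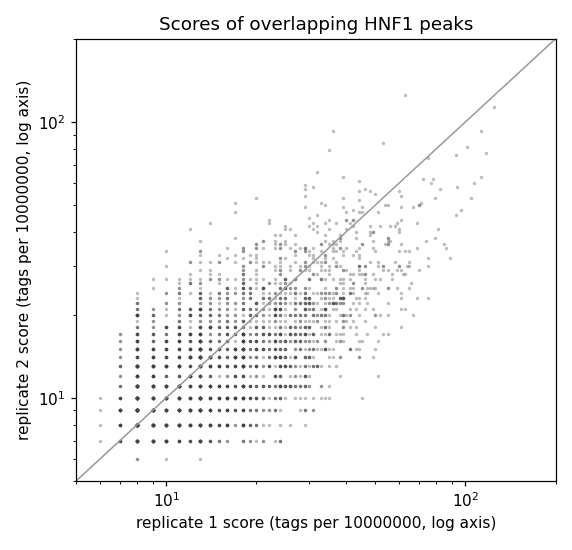
Score of each of the 2907 overlapping pairs in replicate 1 (x axis) and replicate 2 (y axis), in tags scaled to 10000000 per library on log axes, with 1 point per pair and the line of equal scores in grey. The points follow the line with wide scatter, with Spearman's rho of 0.60.

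The next question was whether the replicates placed their sites on the same chromosomes. In both lists chromosome 2 held the most peaks, 567 or 11.2% in replicate 1 and 544 or 10.98% in replicate 2. Relative to the span between first and last peak, shared regions were densest on chromosome 20 at 1.38 per Mb, followed by chromosome 22 at 1.36 and chromosome 17 at 1.32. They were sparsest on chromosome X at 0.373 per Mb. Chromosome Y had 2 peaks in replicate 1 and none in the list of replicate 2. The lists nevertheless differed in their spread over chromosomes (chi-square 64.6, 23 degrees of freedom, permutation p = 1e-05, the smallest these permutations can give).

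Chromosome 20 set the replicates apart. It held 218 peaks of replicate 1, or 4.31% of the list (3.78% to 4.90%), against 119 peaks of replicate 2, or 2.40% (2.01% to 2.87%). This was the 1 chromosome of 24 that passed adjustment (Fisher's exact test, adjusted p = 2.8e-06), and the next lowest adjusted p was 0.24. At an unadjusted level of 0.05, 4 chromosomes passed. Shared peaks count in both lists in these tests, which can hide differences on other chromosomes. Among peaks of 1 replicate alone the chi-square was 143.6 (permutation p = 1e-05). Leaving out the shared peaks takes nearly equal counts from both lists on each chromosome. That raises the statistic by construction, so the higher value does not show a larger difference. Single chromosomes were not tested on those peaks. The 86 shared peaks on chromosome 20 made up 39.4% of the replicate 1 peaks there and 72.3% of the replicate 2 peaks. Between 30 and 70 Mb of this chromosome replicate 1 had 159 peaks and replicate 2 had 78, and between 0 and 30 Mb they had 59 and 41. The cut at 30 Mb was not planned and was not tested. Narrower windows did not follow it, with 19 against 7 peaks at 20 to 30 Mb, 58 against 23 at 30 to 40 Mb and 8 against 7 at 60 to 70 Mb. Without chromosome 20 the lists still differed over the other chromosomes (chi-square 36.6, permutation p = 0.024), and the shares of shared peaks were 58.3% in both replicates. The headers list 6297 putative peaks in replicate 1 and 8280 in replicate 2, of which comparison with the input removed 1161 and 3094. The filter on local signal removed 76 and 229 and that on clonal tags 0 and 2, so the lists kept 80.4% and 59.8%.

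**Figure D3:**
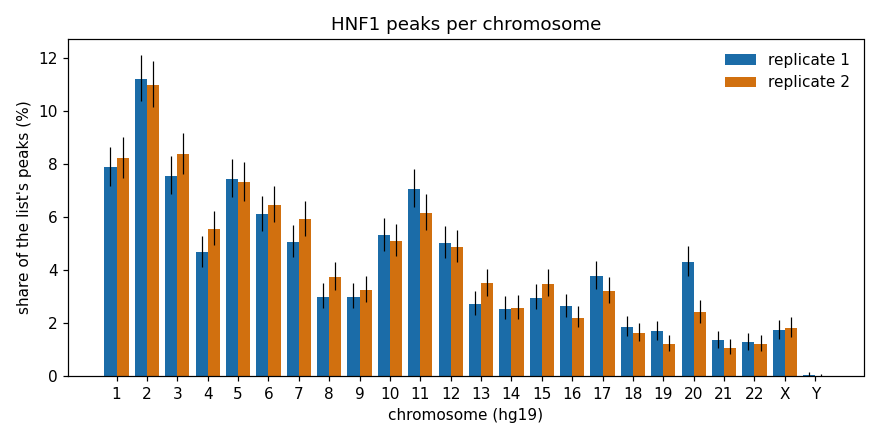
Share of each list's peaks (%, y axis) on each chromosome of hg19 (x axis), for replicate 1 (blue, 5060 peaks) and replicate 2 (orange, 4955 peaks), with Wilson 95% intervals as black bars. Chromosome 20 holds 4.31% of replicate 1 peaks and 2.40% of replicate 2 peaks.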

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

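No alternative that was run raised the p of the overlap, the score correlations or the chromosome difference to 0.05. The overlap tests all gave the smallest p the shifts allow, and Spearman's rho cannot change with log2 scores, so these say little about stability. List sizes fell by construction when the better scored part of each list was kept, to 2530 peaks in replicate 1 and 2477 in replicate 2. The shared share of replicate 1 ranged from 49.9% when 50% of both peaks had to overlap to 61.5% when both lists were reduced to those better scored peaks, and that of replicate 2 from 51.0% to 62.8%. Against the whole of the other list, 78.1% of the better scored peaks of replicate 1 and 78.8% of those of replicate 2 had a partner. Settings chosen after seeing the data were those without chromosome 20, with all peaks set to 200 bp, without the 50 highest scored peaks of each list, with log2 scores, with peaks of 1 replicate alone and with the better scored peaks in the chromosome test. Under these the chromosome difference passed least clearly without chromosome 20 (chi-square 36.6, permutation p = 0.024), followed by the better scored peaks (chi-square 38.1, permutation p = 0.022). The chi-square was largest with peaks of 1 replicate alone (143.6, permutation p = 1e-05), where leaving out the shared peaks raises it by construction. No paired analysis was possible because the inputs entered only through peak calling and each immunoprecipitation has a single list. Leaving out a replicate was not possible for the same reason, since every comparison needs both lists. The planned promoter, motif and gene list tests, with their alternatives, were not run because no hg19 annotation or sequence was used here. The effect of depth was not tested, since the lists give no reads to subsample. A single tag was worth a score of 0.838 in replicate 1 and 0.541 in replicate 2.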

Other observations

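Shared regions of the HNF1 libraries lay in groups along the chromosomes. Of the 2905 shared regions, 299 or 10.3% had another shared region within 10 kb, against a mean of 2.07% and at most 3.41% in 1000 uniform placements within chromosome spans (permutation p = 0.001, the smallest these placements can give). Uniform placement over the chromosome spans is therefore excluded as the whole account of the spacing. Random placement within mappable sequence was not simulated. The uniform placements also fill assembly gaps, which makes them more spread out than mappable sequence allows, and clustering of open chromatin was not tested and stays open.

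The densest group held 11 shared regions on chromosome 2 between 43184361 and 43603296, with median scores of 33 in replicate 1 and 28 in replicate 2. This group includes 2 of the 10 top ranked regions. The median of the highest number within 1 Mb was 7 over the uniform placements, and 1 of the 1000 placements reached 11. A group of 10 on chromosome 10 between 60228412 and 60937904 had median scores of 22 and 23 and contains the fourth ranked region. Another group of 10 lay on chromosome 5 between 123542775 and 124353804, with median scores of 15.5 and 20.5. These windows were picked after their counts were seen.

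The tests on candidate removal and on missing high ranked peaks were chosen after their result was seen. Those on score level, tag ratio, midpoints and spacing were chosen before their own result was seen. The tests on score level and tag ratio concern chromosome 20, which had been picked on these same lists, so they were not planned before the data were examined.

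The peak names number the peaks of each chromosome with gaps, and the highest numbers sum to 6248 in replicate 1 and 8131 in replicate 2, or 99.2% and 98.2% of the putative peaks in the headers, so they were read as given before filtering. Read so, chromosome 20 had 355 putative peaks in replicate 1 (5.68% of all) and 515 in replicate 2 (6.33%), so replicate 2 did not start with a smaller share. Of these, 38.6% were missing from the replicate 1 list and 76.9% from the replicate 2 list (Fisher's exact test p = 4.9e-30). Over all chromosomes the missing share also rose, from 19.0% to 39.1%. The test does not ask whether the rise on chromosome 20 exceeded the rise elsewhere, and putative peaks of a library are not independent replicates. Among the better scored peaks chromosome 20 still held 1.37 percentage points more of replicate 1 (4.07% against 2.70%, Fisher's exact test p = 0.0079). The difference was thus not limited to peaks with low scores. Chromosome 20 had been picked on these same lists, and this p was not adjusted for that choice. The score counts tags and not the fold over input, whereas comparison with the input removed 3094 putative peaks in replicate 2. Peaks near the calling limits over input therefore stay open as a cause. A higher tag level on chromosome 20 in replicate 1 stays open, since the median log2 score ratio of its 86 shared pairs was 0.13 above the rest with a bootstrap interval of 0.03 to 0.50 (permutation p = 0.21), although chromosomes 22, 17, 19, 16, 18 and 9 had higher median ratios (0.61, 0.39, 0.37, 0.36, 0.33 and 0.32, against 0.30) without passing the adjusted test of peak numbers.

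The share of putative peaks missing from the list varied by chromosome alike in both replicates. Across 23 chromosomes, which are not independent replicates, the shares had Spearman's rho of 0.95 and Pearson's r of 0.91 (permutation p = 1e-05 for each, the smallest these permutations can give). Without chromosomes 20 and 21, the extremes in replicate 2, rho was 0.94 and r was 0.90. The shares were 5.21% in replicate 1 and 13.6% in replicate 2 on chromosome 6, but 27.6% and 58.7% on chromosome 11 and 27.7% and 74.8% on chromosome 21. A candidate explanation is that DNA copy number in these aneuploid cells raises tags in immunoprecipitation and input together on some chromosomes, so that more putative peaks form there and fail the input filter. The rho of 0.95 goes with this but also with any other property tied to chromosomes, such as mappability, and the input coverage that would decide was not analysed here.

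The highest scores of replicate 1 included sites with no partner. Of its 50 highest scored peaks, 9 had no overlap in replicate 2, whereas all 50 highest scored peaks of replicate 2 had a partner in replicate 1. Among the 100 highest, 11 and 1 had none, and among the 500 highest, 31 and 15. The top 3 of replicate 1 were among the 9, namely a peak scored 275 on chromosome 21 at 9827366 to 9827508, 1 of 192 on chromosome 12 at 20704355 to 20704497 and 1 of 147 on chromosome 17 at 33478123 to 33478265. Peaks of 121 and 112 lay beside the first, at 9825524 and 9825986, so the 9 are not separate sites throughout. Removal by the filters in replicate 2 may have taken these sites. Of the first 5 peak numbers, 37.1% were missing from replicate 2 on the 7 chromosomes concerned and 46.2% on the 16 others (Fisher's exact test p = 0.42). This count does not look at the 9 sites themselves, so it cannot decide and removal stays open. Reads from multi-copy sequence also stay open and were not tested, and the design gives no biological contrast to test.

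The fragment length of 76 bp used for replicate 1, against 226 bp for replicate 2, could have moved replicate 1 midpoints to either side of the bound site. The midpoint distances argue against this, with 48.0% of pairs at 0 to 25 bp (46.2% to 49.8%) and 20.1% at 50 to 100 bp (18.6% to 21.5%). No biological explanation was tested for this pattern.

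The log2 score ratio of replicate 1 to replicate 2 differed between chromosomes (permutation test on ranks, p = 1e-05, the smallest these permutations can give), with medians from 0 on chromosomes 2, 4, 5 and X to 0.61 on chromosome 22.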
